A study of Homo sapiens with 12 samples.

How the data were processed

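Thymocytes of wild-type, Atm-/- and Chk2-/- mice were given a mock treatment or ionizing radiation at 5 Gy, and RNA was taken 8 h later. Atm is the kinase that starts signalling from DNA double-strand breaks, and Chk2 (gene Chek2) is a kinase that Atm activates. Per the labels, the mice were of a mixed 129SvEv/C57B6 background, total RNA was labelled with biotin, and each sample was hybridized to an Affymetrix mouse expression array with several probe sets for some genes. The 12 arrays form 6 groups of 2, named here by genotype, treatment and the number in the sample titles: 7 and 14 in wild type, 5 and 12 in Atm null, 2 and 3 in Chk2 null. Each number occurs on 1 mock and 1 irradiated array. The labels do not say that a number is an animal, so p-values measure the spread between these samples, which may be technical in part.

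The deposited values were linear probe set signals, that is intensities computed by the authors with GCOS 1.4, per the submitters' processing notes. The table held 22690 probe sets with signals between 0.1 and 92602.3. The trimmed mean of every array lay near 500.2, so the arrays had already been scaled to a common level, and no further normalization was applied in the main setting. Detection calls were not used here. Gene symbols came from the platform annotation: 20380 probe sets had 1 symbol, 691 had several, and 1555 were unnamed here. No gene was named from a probe set with several symbols. The probe set of Bax was among those without a usable name. A mouse genome was not used here, so no positions are given.

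From these intensities log2(signal + 67.3) was computed, the pseudocount being the 25th percentile of all values in the table. A fold change is on that scale and understates the change of dim probe sets. The 64 Affymetrix control probe sets were left out, and a probe set was tested if its signal exceeded the table median of 209.5 on at least 2 of the 12 arrays. That left 13984 probe sets, of which 12718 had 1 symbol, covering 8320 genes. Signals near the filter are close to background, and with 2 arrays per group the number of arrays limits the precision.

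A linear model with a mean for each of the 6 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 6 residual degrees of freedom and a moderated variance that followed the mean signal (5.697 prior degrees of freedom). The contrasts were the radiation response in each of the 3 genotypes, the differences between those responses, and the difference of each null genotype from wild type in the mock arrays, 8 in all. Tests were 2-sided. P-values were adjusted by Benjamini-Hochberg within a contrast, and an adjusted p under 0.05 was called. Standard errors (SE) of log2 changes are those of the fit.

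In all, 21 gene lists were fixed before the data were examined: p53 targets, G2/M genes, DNA replication, homologous recombination and Fanconi genes, end joining, damage signalling, apoptosis, NF-kB targets, interferon response, immediate early genes, heat shock and unfolded protein response, glycolysis and hypoxia, cytosolic ribosome, and markers of double-positive, double-negative and mature single-positive thymocytes, B cells with MHC class II, myeloid cells, erythroid cells, stroma with epithelium, and NK or cytotoxic cells. Of their 587 members 505 had a named probe set. Each gene was represented by its probe set with the highest mean, and a list needed 5 measured members. Camera in limma compared each list with the other genes at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a contrast. The same test with the correlation estimated from the residuals, and fry, were run beside it. With the estimated correlation 1 of the 39 list calls over the 8 contrasts was kept, that of the p53 targets in Chk2 null, and with the array number as a block as well none was called in the 6 contrasts that a block allows. The adjusted p from the estimated correlation stands beside the list calls described. Fry tests whether the genes of a list move on balance in a single direction and does not compare them with other genes.

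Named genes followed a rule fixed before the data were examined. For each contrast they were up to 10 genes per direction with the largest change among called probe sets whose arrays did not overlap between the groups compared (for a difference of responses, whose irradiated minus mock differences did not overlap), or, where none passed, the 3 with the smallest p. Atm and Chek2 were always included on every array. The p53 target genes Cdkn1a, Mdm2, Bbc3, Pmaip1, Ccng1, Trp53inp1, Phlda3, Fas and Aen were always included in the radiation response of each genotype. For each list up to 4 members with the largest called change, or the 2 with the smallest p, were named. Where probe sets of a gene disagreed, this is stated.

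Whether the numbers pair the samples was checked on the deviations of arrays from their group means. The mock and irradiated arrays of the same number deviated together, with a correlation across probe sets of 0.42 in wild type, 0.51 in Atm null and 0.27 in Chk2 null. All 3 lay above 0.1, so the numbers were taken to pair the arrays in the blocked fits, while the main fit left them out. Each genotype gives a single such value, which can be positive without a pairing, so the check is weak. In 2 arrays per group this correlation and the group mean come from the same values. The model with the number as a fixed block has 3 residual degrees of freedom. For the mock comparisons, where a fixed block cannot be fitted, the number was a random block with a correlation of 0.363.

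The model was tested on simulated data with the spread of the real arrays. For the wild-type response, 58% of 100 probe sets changed by 1 log2 unit and 97% of 100 changed by 2 were recovered, with 11 false calls among 166. For the difference between Chk2 null and wild type the shares were 11% and 77%, with 5 false calls among 93. When the p53 list was shifted by 0.4 in simulated wild-type data, 1 list was called. Probe sets were drawn independently of each other and without differences in brightness between arrays. The simulated shares and false calls therefore give no error rate for the real arrays.

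Alternatives fixed beforehand were pseudocounts of 1 and 209.5, no filter, a filter at the 75th percentile, quantile normalization, no variance trend, only the arrays of a contrast, each array left out in turn, the number as a block, the estimated correlation, fry, the mean of all probe sets of a gene, and other thresholds for the wild-type calls. Chosen after seeing the data were the mean log2 signal of the 18 hybridization spike-in probe sets as a covariate, the log2 ratio of the 3' to the 5' beta-actin control probe set as a covariate, the block together with the estimated correlation, the genes called in wild type beside all genes on the same side of 209.5 in mock wild type, and leaving out 3 arrays with high spike-in signals together (mock Chk2 null 3, irradiated Atm null 12 and irradiated wild type 7). That fit kept irradiated wild type 14, whose spike-in level, at 2.93 times the lowest, lay above those of the first 2 arrays left out, since without it no irradiated wild-type array would remain. The spike-ins are bacterial transcripts added to the hybridization mix at fixed amounts, so after scaling a high spike-in signal marks an array whose sample was dim.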

Results

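Gene expression was measured on 12 arrays of mouse thymocytes, the immature T cells of the thymus, from wild-type, Atm null and Chk2 null mice, 8 h after a mock treatment or 5 Gy of ionizing radiation, with 2 arrays in each of the 6 groups. The design asks how the transcriptional response to radiation depends on the kinases Atm and Chk2, and the study's title concerns Chk2 and damage arising during DNA replication. Signals of the 2 arrays of a group correlated across probe sets with r between 0.911 and 0.975.

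The targeted genes were read first. The Atm probe set gave 159 ± 13.6 (mean signal ± SD, n = 2) in mock wild type, 96.1 ± 27.9 in mock Atm null and 190 ± 7.99 in mock Chk2 null. The log2 difference between Atm null and wild type, -0.48 ± 0.28 (SE), was not called by limma (adjusted p = 0.846). Array by array the Atm signal was 149.5 and 168.7 in mock wild type 7 and 14, 210.1 and 308.2 in irradiated wild type 7 and 14, 76.4 and 115.8 in mock Atm null 5 and 12. It was 132.1 and 91 in irradiated Atm null 5 and 12, 184 and 195.3 in mock Chk2 null 2 and 3, and 192.1 and 174.5 in irradiated Chk2 null 2 and 3. The Chek2 probe set gave 236 ± 21.6 in mock wild type and 395 ± 43.9 in mock Chk2 null, a log2 difference of 0.61 ± 0.21 (adjusted p = 1 by limma). On single arrays the Chek2 signal was 251.5 and 221 in mock wild type 7 and 14, 410.8 and 424.1 in irradiated wild type 7 and 14, 247.2 and 294.4 in mock Atm null 5 and 12. It was 200.1 and 267.2 in irradiated Atm null 5 and 12, 364.2 and 426.3 in mock Chk2 null 2 and 3, and 465 and 346.2 in irradiated Chk2 null 2 and 3. The position of either probe set relative to the deleted part of its gene is not known here, so these signals check neither genotype.

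The arrays differed in brightness in a way that followed some of the groups. Spike-in signals on the irradiated wild-type arrays 7 and 14 were 3.21 and 2.93 times those of the lowest array, against 1.20 and 1.39 on the mock wild-type arrays. Irradiated Atm null 12 stood at 2.21 and mock Chk2 null 3 at 2.27, while irradiated Chk2 null arrays stood at 1.06 and 1.11. The 3' to 5' beta-actin ratio, which rises when RNA is degraded or poorly copied, was 1.86 ± 0.113 (SD, n = 2) in irradiated against 1.34 ± 0.0737 in mock wild type. It was 1.83 ± 0.344 against 1.30 ± 0.0932 in Atm null, and 1.42 ± 0.0834 against 1.51 ± 0.198 in Chk2 null.

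**Figure D1:**
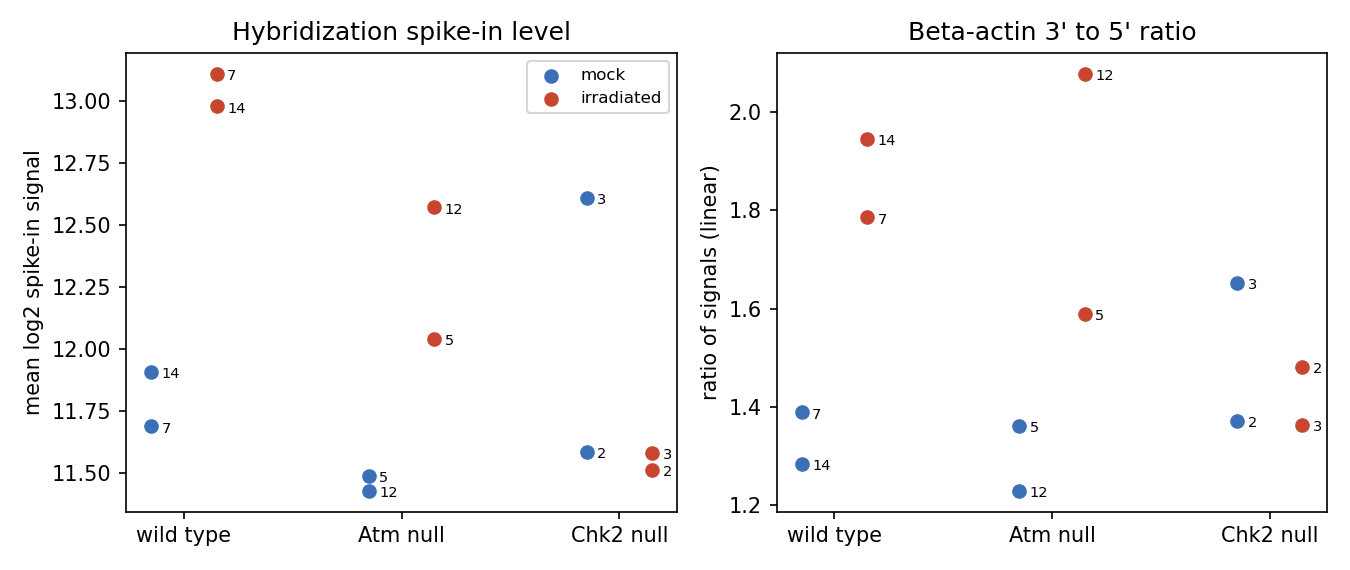
Mean log2 signal of the hybridization spike-in probe sets (left) and the linear ratio of 3' to 5' beta-actin signal (right) on each of the 12 arrays, by genotype and treatment, each point an array marked with its number. Both irradiated wild-type arrays lie above all other arrays in spike-in level, at 13.11 and 12.98.

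In irradiated wild-type thymocytes p53 target genes rose. Aen, an exonuclease gene induced in apoptosis, went from 423 ± 108 (mean signal ± SD, n = 2) to 1836 ± 130, a log2 change of 1.97 ± 0.20 (SE). Bbc3, which encodes the proapoptotic BH3-only protein Puma, rose by 1.90 ± 0.26, Plk2 by 1.88 ± 0.41, and the cell cycle inhibitor Cdkn1a by 1.83 ± 0.26. Phlda3 (1.83 ± 0.27), Ccng1 (1.63 ± 0.24), Pmaip1 (1.28 ± 0.38) and Trp53inp1 (0.69 ± 0.14) also rose, with adjusted p in limma between 0.00111 for Aen and 0.0444 for Pmaip1. The Pmaip1 signal exceeded the filter signal of 209.5 only on the irradiated wild-type arrays. This gene was thus tested only through the group in which it was high. The probe sets of Mdm2 disagreed, the brighter one at 0.32 ± 0.29 (adjusted p = 0.455 in limma) and the other at 0.67 ± 0.15 (adjusted p = 0.0214 in limma). Fas (0.26 ± 0.38, adjusted p = 0.644) did not pass. Of 37 measured p53 targets 21 rose and none fell, 24 when adjusted over the list alone. The list's median was 0.90 and its camera adjusted p was 3.77e-10 (adjusted p = 0.0911 with an estimated correlation). Beside this group the spike-in level rose by 1.25 log2 units and the log2 actin ratio by 0.48.

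**Figure D2:**
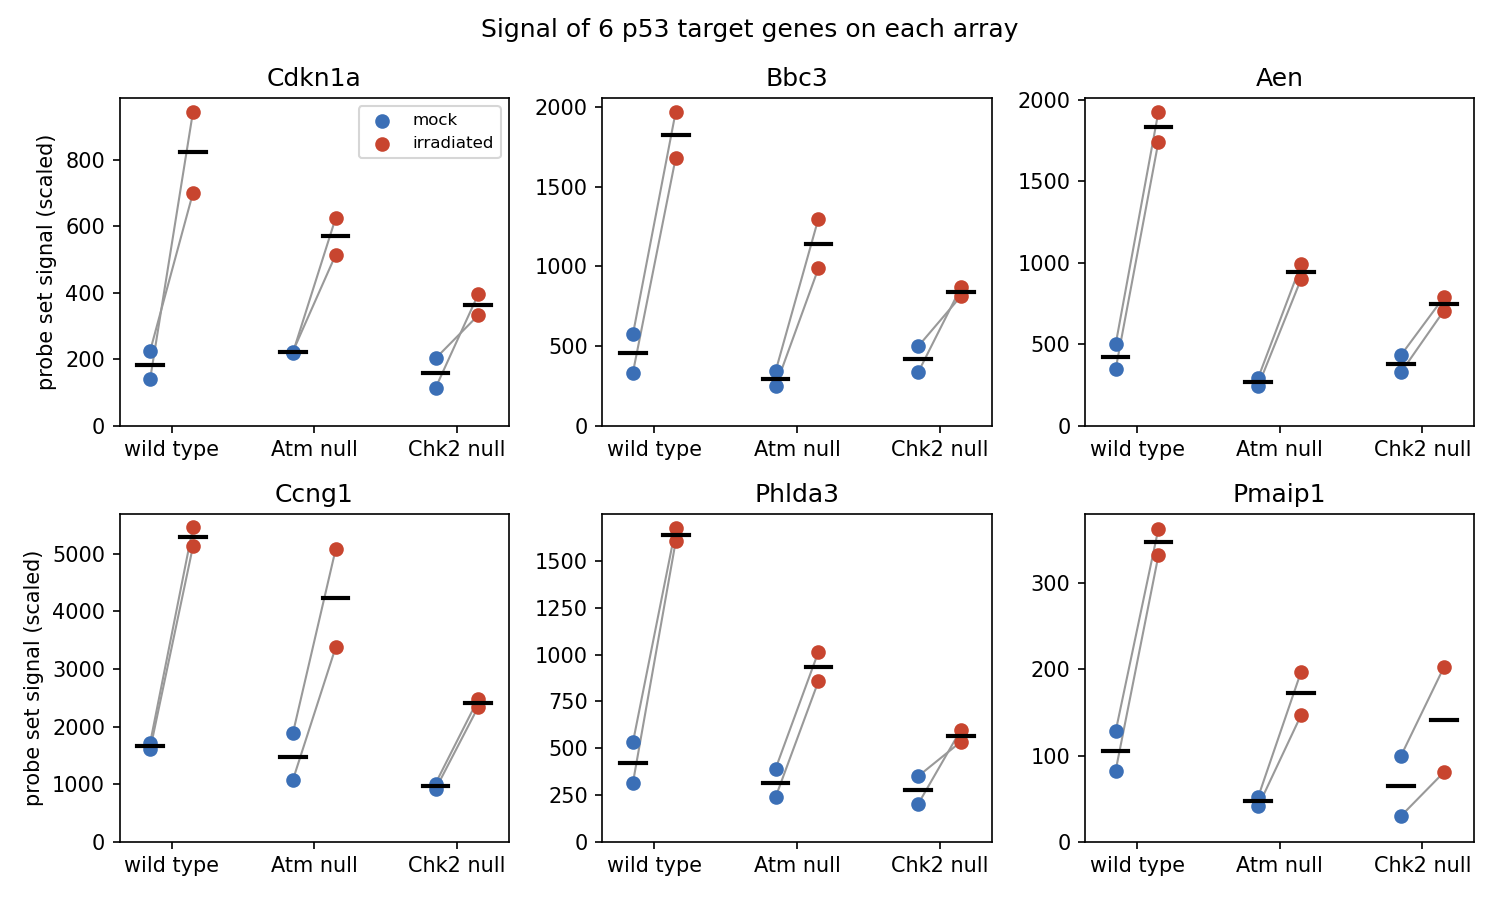
Scaled linear signal of 1 probe set each of Cdkn1a, Bbc3, Aen, Ccng1, Phlda3 and Pmaip1 on every array, by genotype and treatment. Points are arrays, grey lines join the mock and irradiated array of the same number, and black bars are means of 2 arrays; for Aen the irradiated means were 1836 in wild type, 945 in Atm null and 746 in Chk2 null.

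Genes of mitosis and DNA replication fell in irradiated wild type. Of 34 G2/M genes 27 fell and none rose, 30 when adjusted over the list alone, among them Ube2c (-2.07 ± 0.26), Kif23 (-1.83 ± 0.55), Cenpa (-1.73 ± 0.22) and Ccnb2 (-1.70 ± 0.22). Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, went from 4503 ± 545 (mean signal ± SD, n = 2) to 1094 ± 586. Of 44 DNA replication genes 14 fell and none rose, 25 when adjusted over the list alone, including the polymerase gene Pole (-1.61 ± 0.29), Uhrf1 (-1.38 ± 0.22), Dbf4 (-1.37 ± 0.22) and Tk1 (-1.16 ± 0.29). The medians were -1.20 and -0.56, with camera adjusted p of 3.5e-24 and 3.77e-10 (adjusted p = 0.244 and 0.287 with an estimated correlation). The mean log2 signal of the G2/M list was 9.17 on irradiated array 7 and 9.88 on irradiated array 14, against 10.53 and 10.9 on the mock arrays, and irradiated array 7 had the lowest mean correlation with the other arrays (r = 0.860 across probe sets). On the same arrays the spike-in level rose by 1.25 log2 units and the log2 actin ratio by 0.48, and myeloid, B cell with MHC class II and mature single-positive markers had medians of 0.76, 0.54 and 0.41.

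Outside these lists the largest rises were those of Ltbr (2.40 ± 0.28), Sccpdh (2.22 ± 0.46), Nfib (2.15 ± 0.52), Ptp4a3 (2.08 ± 0.22) and Dpysl5 (2.07 ± 0.47). Next came Col6a1 (2.06 ± 0.40), Mrgpra3 (2.01 ± 0.48), Flvcr2 (1.99 ± 0.42) and Src (1.97 ± 0.55). Apart from the phosphatase gene Ptp4a3, which went from 737 ± 72.4 (mean signal ± SD, n = 2) to 3418 ± 1152, these genes were dim in the mock arrays, with means between 15.05 for Dpysl5 and 66.85 for Mrgpra3. Dpysl5, Nfib, Col6a1 and Src exceeded the filter signal of 209.5 only on the irradiated wild-type arrays. They were thus tested only through the group in which they were high. The largest falls were those of Cyb5r3 (-2.35 ± 0.23), the anaphase activator Cdc20 (-2.21 ± 0.32), the granzyme gene Gzma (-2.17 ± 0.50), Smarcb1 (-2.14 ± 0.33) and the importin gene Kpna2 (-2.11 ± 0.32). After Ube2c came Trim37 (-2.02 ± 0.43), Tbpl1 (-1.95 ± 0.23), the cohesin protector Sgo1 (-1.94 ± 0.44) and Rfc4 (-1.90 ± 0.35, another probe set at -0.67). Other probe sets of Cyb5r3 (0.26 and 0.08), Smarcb1 (-0.15) and Trim37 (0.37 and 0.30) did not follow. Several of these genes fell to signals below 209.5, close to background, on irradiated arrays 7 and 14. They were Cyb5r3 (27.8 and 43.5), Cdc20 (15.8 and 16.1), Smarcb1 (33.7 and 44), Trim37 (28.9 and 72.2), Tbpl1 (80.6 and 149) and Rfc4 (21.7 and 136.8).

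In all, limma with Benjamini-Hochberg adjustment called 2076 of 13984 probe sets in wild type, 1162 higher and 914 lower, or 954 genes higher and 663 lower. Of the higher calls 55.9% had a mean mock signal below 209.5, against 1.31% of the lower calls and 23.6% of all probe sets tested. The split turned to 564 higher and 872 lower with quantile normalization, 295 and 811 with the stricter filter, and 629 and 800 with a pseudocount of 1. With a pseudocount at the median it was 1635 higher and 980 lower. With the array number as a block 4713 probe sets were called, including all 2076. With the spike-in level or the actin ratio as a covariate, or with only the 4 wild-type arrays in the fit, limma called 0 (4880 at an unadjusted p under 0.05 in the fit of all arrays). Without mock array 14, mock array 7 or irradiated array 7 it called 42, 567 and 271 probe sets.

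In Atm null thymocytes limma called no single probe set after irradiation (0 at an adjusted p under 0.05, 1281 at an unadjusted p under 0.05 where 699 would pass by chance, smallest adjusted p 0.0611). The p53 targets shifted as a list, with a median of 0.46, 33 of 37 members positive and 13 passing when adjusted over the list alone (camera adjusted p = 3.29e-11, and adjusted p = 0.0699 with an estimated correlation). Bbc3 had a log2 change of 1.74 ± 0.26 (SE), Aen 1.59 ± 0.20, Ccng1 1.5 ± 0.24 and Phlda3 1.42 ± 0.27, with adjusted p in limma of 0.102, 0.0611, 0.161 and 0.228. On arrays 5 and 12 the signal went from 219.2 and 223.2 in mock to 624.9 and 514.2 for Cdkn1a. It went from 52.5 and 41.6 to 197.3 and 147 for Pmaip1, and from 8100 and 8020.3 to 13294.6 and 11120.8 for Trp53inp1. For Fas it went from 911.7 and 279.5 to 1308.6 and 978.1. The brighter Mdm2 probe set went from 1088.7 and 803.5 to 1438.1 and 813.2, the other from 761.2 and 774.9 to 849.9 and 765.8. The G2/M list shifted lower, with a median of -0.35 and 2 of 34 members positive (camera adjusted p = 3.79e-12, and adjusted p = 0.686 with an estimated correlation). Its members with the smallest p were the kinetochore gene Cenpf (-1.12 ± 0.20, adjusted p = 0.183, another probe set at 0.15) and the mitotic kinase gene Plk1 (-0.84 ± 0.18, adjusted p = 0.252). The other genes nearest to a call were Lsm4 (-0.84 ± 0.17) and Vim (-0.71 ± 0.15, other probe sets at 0.16 and 0.10).

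The DNA replication list was not called in Atm null, with a median of -0.02 and a camera adjusted p of 0.291. With the array number as a block limma called 102 probe sets, 72 higher and 30 lower, among them Bbc3, Aen, Ccng1 and Phlda3, with blocked adjusted p of 0.00138, 0.00138, 0.00013 and 0.0147. In the blocked fit 7 p53 targets were higher and 3 G2/M genes lower, and the myeloid list (median 0.36) passed camera with an adjusted p of 0.0266, against 0.108 unblocked (adjusted p = 0.574 with the block and an estimated correlation). Beside these groups the spike-in level rose by 0.85 log2 units and the log2 actin ratio by 0.49.

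In Chk2 null thymocytes the p53 targets again shifted higher as a list after irradiation, and this call was kept with an estimated correlation but not when the array number was a block as well. The median was 0.48, with 29 of 37 members positive and 11 passing when adjusted over the list alone (camera adjusted p = 1.31e-20, and adjusted p = 0.0133 with an estimated correlation, 0.127 with the block added). Ccng1 had a log2 change of 1.27 ± 0.24 (SE), Ei24 1.05 ± 0.16, Cdkn1a 0.96 ± 0.26, Bbc3 0.93 ± 0.26 and Aen 0.87 ± 0.20 (another probe set at 1.89), none called singly. On arrays 2 and 3 the signal went from 203.2 and 351 in mock to 600 and 535.5 for Phlda3. It went from 99.7 and 30 to 202.2 and 80.6 for Pmaip1, and from 9622.8 and 10588.2 to 11745.8 and 12218.7 for Trp53inp1. For Fas it went from 727.2 and 763.4 to 888.9 and 1139.6. The brighter Mdm2 probe set went from 1289.6 and 721.5 to 1200.8 and 1566.7, the other from 795.2 and 728.8 to 1031.7 and 928.2. The DNA replication list shifted higher, with a median of 0.31 and 41 of 44 members positive (camera adjusted p = 4.46e-19, and adjusted p = 0.178 with an estimated correlation). No member passed alone; the nearest were the thymidine kinase gene Tk1 (0.78 ± 0.29) and the ribonucleotide reductase gene Rrm2 (0.84 ± 0.36). Homologous recombination and Fanconi genes had a median of 0.14 (camera adjusted p = 0.0411, 0.0857 with the block, and adjusted p = 0.178 with an estimated correlation), led by Brca1 (0.67 ± 0.22) and Rad51ap1 (0.55 ± 0.17). That call ended without mock array 2 (adjusted p = 0.563), irradiated array 2 or 3 (0.0754 and 0.0825), or irradiated Atm null 5 or 12 (0.0516 and 0.0525), and was kept in 14 of 23 other settings.

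The G2/M list was not called in Chk2 null, with a median of 0.02 and a camera adjusted p of 0.775. For single probe sets limma called 0, with a smallest adjusted p of 0.243. At an unadjusted p under 0.05 there were 323, fewer than the 699 that would pass by chance. The spread in this fit came from all 6 groups. The 2 irradiated arrays correlated with r = 0.975 in Chk2 null and r = 0.911 in wild type. Counts of calls therefore do not compare the genotypes at their own spread. Genes nearest to a call also included Dglucy (1.83 ± 0.31), Gdf2 (-1.60 ± 0.27), Ift172 (-1.16 ± 0.28) and Pdrg1 (-0.61 ± 0.16, another probe set at -0.07). With the array number as a block 7 probe sets were called, all higher, among them probe sets of Aen, Dglucy, Ccng1 and Ei24 (blocked adjusted p = 0.0153, 0.00862, 0.000903 and 0.0102). With the block markers of double-positive thymocytes (median 0.10) also passed camera, with an adjusted p of 0.0283, against 0.0895 unblocked (adjusted p = 0.626 with the block and an estimated correlation). The mock array 3 of this genotype was among the dim ones.

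**Figure D3:**
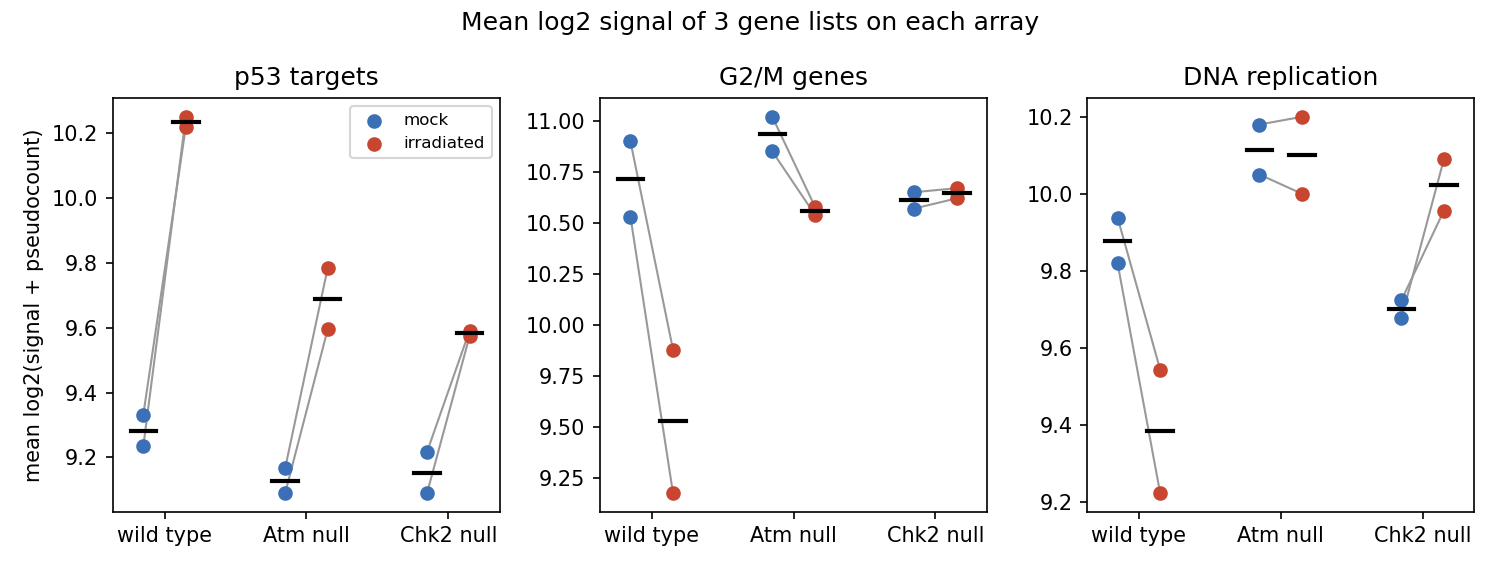
Mean log2(signal + pseudocount) over the measured members of the p53 target, G2/M and DNA replication lists on each array, by genotype and treatment, with lines joining arrays of the same number and black bars for means of 2 arrays. The mean change in the p53 list was 0.95 in wild type, 0.56 in Atm null and 0.43 in Chk2 null, and that of the replication list was -0.50, -0.01 and 0.32.

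The response of Atm null was compared with that of wild type by testing the difference itself. G2/M genes (median difference 0.80, 31 of 34 positive, 14 passing when adjusted over the list alone) and DNA replication genes (0.50, 40 of 44 positive) were shifted higher relative to wild type, and p53 targets lower (-0.31, 9 of 37 positive). Camera adjusted p was 1.75e-18, 3.54e-12 and 0.000279, and with an estimated correlation the adjusted p was 0.343, 0.343 and 0.342. Damage signalling genes (0.27, camera adjusted p = 0.0131, and 0.342 with an estimated correlation) were called as a list, led by H2ax (1.05 ± 0.25, SE). So were double-positive thymocyte markers (0.13, adjusted p = 0.0438, and 0.446 with an estimated correlation) and cytosolic ribosome genes (0.12, adjusted p = 0.028, and 0.626 with an estimated correlation). Leaving out 1 array ended these 3 calls. For damage signalling it was irradiated Atm null 12, mock Atm null 5 or mock wild type 14 (adjusted p = 0.0802, 0.0933 and 0.0559). For the double-positive markers it was irradiated Atm null 5, mock Atm null 12, irradiated wild type 14 or 7 or mock wild type 14 (0.118, 0.366, 0.0818, 0.0891 and 0.061). For the ribosome it was mock Atm null 5 or irradiated wild type 14 (0.616 and 0.319), and its median turned to -0.06 without irradiated Atm null 12 (0.901). Over 24 other settings the damage signalling call was kept in 19, the double-positive call in 14, with losses under quantile normalization and the spike-in covariate, and the ribosome call in 17, with losses under quantile normalization.

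Single genes nearest to a call in that difference were Hmgb2 (1.58 ± 0.19, adjusted p = 0.0522 in limma), Rassf1 (1.75 ± 0.25) and the cytokinesis gene Ect2 (1.70 ± 0.27). On the lower side were Eml5 (-2.87 ± 0.58, other probe sets at -0.60 and 0.73), Col6a1 (-2.70 ± 0.56) and Ei24 (-1.03 ± 0.23). For single probe sets limma called 0, with 1197 at an unadjusted p under 0.05, and 253 with the array number as a block (222 higher, 31 lower). The block also brought camera calls lower in Atm null for NF-kB targets (-0.23, adjusted p 0.0371), double-negative (-0.32, 0.0153) and mature single-positive thymocyte markers (-0.31, 0.0371) and myeloid markers (-0.39, 0.0111). With the block and an estimated correlation the adjusted p of these 4 lists was 0.269, 0.264, 0.353 and 0.358. Without irradiated wild type 14 limma called 58. Irradiated over mock, the spike-in signal had a fold of 2.37 in wild type and 1.80 in Atm null, and the actin ratio one of 1.39 and 1.4.

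Between Chk2 null and wild type the responses differed for cell cycle genes. G2/M genes were higher relative to wild type, with a median difference of 1.35, all 34 members positive, 7 passing and 24 when adjusted over the list alone. DNA replication genes had a median of 0.89, 39 of 44 positive, 3 passing and 26 over the list alone. Among the called genes were the mitotic kinase Cdk1 (1.93 ± 0.38, SE), Nusap1 (1.86 ± 0.32, another probe set at -0.45), Ube2c (1.86 ± 0.37) and Cdca3 (1.78 ± 0.30). Of the replication genes they were Uhrf1 (1.73 ± 0.31), the histone mRNA-binding Slbp (1.71 ± 0.26) and Dut (1.23 ± 0.23). Cdk1 went from 2533 ± 497 (mean signal ± SD, n = 2) to 784 ± 404 in wild type and from 2241 ± 38.2 to 2677 ± 247 in Chk2 null. The p53 targets were lower (-0.50, 8 of 37 positive), with Tnfrsf10b (-2.27 ± 0.58) and Aen (-1.10 ± 0.28, another probe set at 0.00) nearest to a call. Camera adjusted p was 1.91e-22, 7.64e-17 and 0.00639, and with an estimated correlation the adjusted p was 0.368 for all 3 lists. On average the arrays of the 2 genotypes moved in opposite ways with radiation. Irradiated over mock, the spike-in signal had a fold of 2.37 in wild type and 0.683 in Chk2 null, and the actin ratio one of 1.39 and 0.944. The Chk2 null folds rested on mock array 3. In array pair 2 of Chk2 null the log2 spike-in level went from 11.58 to 11.51, and the actin ratio rose from 1.37 to 1.48. With the spike-in covariate the mean difference of G2/M genes went from 1.22 ± 0.335 (SE) to 1.11 ± 0.665, within 2 SE of 0, and with the actin ratio to 1.26 ± 0.534. That of replication genes went from 0.819 ± 0.18 to 0.977 ± 0.348 and 1.05 ± 0.25, and that of p53 targets from -0.524 ± 0.107 to -0.511 ± 0.213 and -0.552 ± 0.17.

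Further genes called higher were Foxm1 (2.62 ± 0.50, other probe sets at -0.08 and -0.38), Cyb5r3 (2.58 ± 0.32, others at -0.26 and -0.32) and the ribonucleotide reductase gene Rrm1 (2.15 ± 0.33). They were followed by Tbpl1 (2.15 ± 0.33), Cks2 (1.92 ± 0.29), Fen1 (1.91 ± 0.35, another at -0.53), Zfp746 (1.88 ± 0.33) and Nucb1 (1.86 ± 0.35). On irradiated wild type 7 and 14 some of these lay below the filter signal of 209.5, close to background. They were Foxm1 (42.8 and 31.5), Cyb5r3 (27.8 and 43.5), Tbpl1 (80.6 and 149), Zfp746 (47.4 and 80.9) and Nucb1 (56 and 105). In Chk2 null 2 and 3 Foxm1 stood at 96.5 and 40.2 in mock and at 138.5 and 320.3 after irradiation. Called lower were Flvcr2 (-3.39 ± 0.59), Zfp651 (-2.83 ± 0.41), Ltbr (-2.64 ± 0.40), Tmem144 (-2.31 ± 0.42) and Gdf2 (-2 ± 0.38). Smaller falls in the difference were those of Ccr6 (-1.78 ± 0.34), Uqcr10 (-1.61 ± 0.29, others at -0.53 and 0.66), Pdrg1 (-1.54 ± 0.23, another at 0.14) and Clcn5 (-1.51 ± 0.30). Adjusted p in limma lay between 0.0307 and 0.0497 over these genes. Double-positive thymocyte markers (0.16, camera adjusted p = 0.0349), B cell and MHC class II genes (-0.49, 0.0454) and myeloid markers (-0.73, 0.0298) were called as lists (adjusted p = 0.424, 0.368 and 0.424 with an estimated correlation). Each of these 3 calls ended without irradiated wild type 14 (adjusted p = 0.0593, 0.0593 and 0.183). The double-positive call also ended without irradiated wild type 7, mock Chk2 null 3 or irradiated Chk2 null 2 (0.0631, 0.0664 and 0.0586). That of B cells and MHC class II ended without irradiated wild type 7, mock wild type 14, mock Chk2 null 2 or irradiated Chk2 null 3 (0.0789, 0.105, 0.127 and 0.107). The myeloid call ended without mock wild type 7, mock Chk2 null 2 or irradiated Chk2 null 3 (0.0579, 0.187 and 0.192). Over 24 other settings these calls were kept in 15, 16 and 19. The double-positive call was lost with quantile normalization, the stricter filter, either covariate and without the 3 dim arrays, its median falling as low as -0.08, and with the spike-in covariate its mean difference went from 0.24 ± 0.09 to -0.004 ± 0.13.

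Limma called 83 probe sets in all, 70 higher and 13 lower, while the 3314 at an unadjusted p under 0.05 were 1314 higher and 2000 lower. Quantile normalization moved the median of all probe sets in this difference from -0.09 to 0.02. With the array number as a block 2210 probe sets were called, 1116 higher and 1094 lower, all 83 among them. With the block damage signalling genes (median 0.29, camera adjusted p 0.0381), double-negative (-0.63, 0.0199) and mature single-positive markers (-0.39, 0.0152) were called too (adjusted p = 0.296, 0.296 and 0.348 with the block and an estimated correlation). With the spike-in or actin covariate, without the 3 dim arrays, or with only the arrays of the contrast limma called 0. It also called 0 without mock wild type 7 or 14, mock Chk2 null 3 or irradiated Chk2 null 2 or 3. It called 1 without irradiated wild type 7, 400 without irradiated wild type 14 and 1318 without mock Chk2 null 2.

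The responses of Chk2 null and Atm null were set against each other in the same way. G2/M genes (median difference 0.41, 28 of 34 positive) and DNA replication genes (0.32, 38 of 44 positive) had a higher response in Chk2 null. Camera adjusted p was 1.37e-09 and 1.43e-09 (adjusted p = 0.793 for both with an estimated correlation). The mean log2 signal of the replication list was 9.68 and 9.72 in mock Chk2 null, and 10.05 and 10.18 in mock Atm null. After irradiation it was 10.09 and 9.96 against 10 and 10.2, so the replication difference lay in the mock arrays. That of G2/M genes was 10.65 and 10.57 against 10.85 and 11.02 in mock. After irradiation it was 10.67 and 10.62 against 10.54 and 10.58. The p53 list was not called by camera (-0.10, adjusted p = 0.718). Irradiated over mock, the spike-in signal had a fold of 1.80 in Atm null and 0.683 in Chk2 null, and the actin ratio one of 1.4 and 0.944. The mean difference of G2/M genes, 0.412 ± 0.335 (SE), lay within 2 SE of 0, as it did with the spike-in level (0.325 ± 0.566) or the actin ratio (0.45 ± 0.539) as a covariate. That of replication genes, 0.335 ± 0.18, also lay within 2 SE of 0, and was 0.459 ± 0.297 with the spike-in level and 0.568 ± 0.253 with the actin ratio. Single genes nearest to a call were Cdca5 (1.08 ± 0.21, SE), Sdhd (1.29 ± 0.32, another probe set at -0.29), Ube2v1 (0.85 ± 0.21), Sfrp1 (-3.33 ± 0.53), Hnrnpa2b1 (-1.17 ± 0.21, others between -0.63 and 0.02) and Gdf2 (-2.13 ± 0.38). Limma called 0 (851 at an unadjusted p under 0.05, smallest adjusted p 0.572), and 1 with the array number as a block, Sfrp1 (blocked adjusted p = 0.0492).

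Genes called in wild type were followed into the null genotypes. The 954 genes that rose in wild type had a median log2 change of 0.44 in Atm null, 92.6% of them positive against 57.8% of all genes, and of -0.08 in Chk2 null, 38.4% positive against 47.6%. The 663 that fell had medians of -0.22 and 0.05. Irradiated over mock, the spike-in signal had a fold of 2.37 in wild type, 1.80 in Atm null and 0.683 in Chk2 null. Among all genes with a mean mock wild-type signal below 209.5, 83.9% were positive in Atm null and 34.3% in Chk2 null, with medians of 0.39 and -0.11. The 533 of the 954 genes below that signal had 92.3% and 38.8% positive. The 421 at or above it had 92.9% and 37.8%, against 49.8% and 51.7% of all genes there. The medians differed between Chk2 null and Atm null by -0.50 and 0.29 (camera p = 2.13e-20 and 1.78e-29, p = 0.124 and 0.0362 with an estimated correlation, p = 0.0759 and 0.0647 by fry). With the spike-in level as a covariate the mean difference of the genes that rose went from -0.498 ± 0.23 (SE) to 0.0108 ± 0.25, and with the actin ratio to -0.25 ± 0.337. That of the genes that fell went from 0.298 ± 0.133 to 0.0943 ± 0.192 and 0.235 ± 0.211. All 4 values with a covariate lay within 2 SE of 0. The mean change of both sets in Atm null also came within 2 SE of 0 with the spike-in level or the actin ratio, at 0.132 ± 0.163 and 0.228 ± 0.266 for genes that rose and -0.104 ± 0.125 and -0.174 ± 0.167 for those that fell. Without mock Chk2 null 3 the Chk2 null medians were 0.18 and -0.06. The first was -0.38 without mock Chk2 null 2. These fits called the wild-type genes anew, so their sets were not exactly the 954 and 663 genes. The smaller set called higher without mock wild type 14 had a median of 0.87 in Chk2 null. For the 954 genes themselves the Chk2 null median was 0.12 in array pair 2 and -0.25 in pair 3. No call was shared between genotypes in the unblocked fit, where both null responses had 0 calls. With the block, wild type and Atm null shared 42 higher and 23 lower calls, where independent lists would share 13.9 and 4.32. All 7 Chk2 null calls were shared with wild type and with Atm null (Fisher's exact test across probe sets, which are not independent, p = 2.64e-13, 2.85e-14, 9.94e-06 and 7.11e-17).

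Without radiation, few genes separated the genotypes. Rpgrip1, a gene of photoreceptor cilia, was higher in both null genotypes, at 1883 ± 352 (mean signal ± SD, n = 2) in Atm null and 1399 ± 70.8 in Chk2 null against 196 ± 29.8 in wild type. The log2 differences were 2.88 and 2.48 (SE 0.17 each, adjusted p = 1.82e-05 and 9.75e-05 in limma). Ivns1abp was lower in both (-1.36 and -1.29, SE 0.17 each, adjusted p = 0.0223 and 0.0229). Atp6v1d, a subunit gene of the vacuolar proton pump, was lower in Atm null (-1.62 ± 0.13), Khdrbs1 was lower in Chk2 null (-2.19 ± 0.28, other probe sets between -0.81 and -0.44) and Ubxn11 higher there (1.79 ± 0.22). In mock Atm null, markers of mature single-positive thymocytes were lower as a list, with a median of -0.52, 1 of 22 members positive and 9 passing when adjusted over the list alone. The leading members were Gimap4 (-1.79 ± 0.26, adjusted p = 0.06) and the homing receptor Ccr7 (-1.57 ± 0.27, adjusted p = 0.0926). B cell and MHC class II genes were lower too (-0.47, 0 of 15 positive, 4 over the list alone), with H2-Aa (-1.35 ± 0.31) and Cd74 (-1.13 ± 0.28). Camera adjusted p was 1.21e-12 and 4.07e-08 (adjusted p = 0.065 for both with an estimated correlation).

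Other list shifts in mock cells were smaller. In Atm null, double-positive markers had a median of -0.22, with Slfn2 (-0.87 ± 0.19) and Satb1 (-0.49 ± 0.16) leading. Replication genes had 0.27 and G2/M genes 0.26 (for the 3 lists, camera adjusted p = 0.00114, 3.6e-08 and 2.5e-06, and adjusted p = 0.409, 0.409 and 0.456 with an estimated correlation). The first call ended without mock Atm null 12 (adjusted p = 0.425) and the G2/M call without mock wild type 7 (0.414). In Chk2 null, replication genes had a median of -0.17, p53 targets -0.11, G2/M genes -0.11, ribosome genes -0.10 and immediate early genes 0.18, with Egr3 (1.02 ± 0.27) leading. In this order the camera adjusted p was 1.02e-05, 0.0197, 0.02, 0.0236 and 0.0236 (adjusted p = 0.729 for all with an estimated correlation). Without mock wild type 14 the replication (adjusted p = 0.082), G2/M (0.491, median 0.04), ribosome (0.082) and immediate early (0.34) calls ended. Without mock wild type 7 the p53 (0.073) and ribosome (0.0789) calls ended. Without mock Chk2 null 2 it was the p53 (0.255), ribosome (0.0527) and immediate early (0.312) calls, and without mock Chk2 null 3 the G2/M (0.628) and ribosome (0.378) calls. Over 23 other settings the Chk2 null calls were kept in 22 for replication, 20 for p53 targets, 17 for G2/M genes, 16 for the ribosome and 18 for immediate early genes.

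Limma called 3 probe sets in Atm null and 5 in Chk2 null. Those at an unadjusted p under 0.05 were 856 and 465, where 699 would pass by chance. With the array number as a random block limma called 9 and 6. In Atm null it called 9 without mock Atm null 5, and in Chk2 null 1 without mock wild type 7 or mock Chk2 null 3, 2 without mock wild type 14 and 3 without mock Chk2 null 2. Both comparisons used the same mock wild-type arrays and shared 2 calls, Rpgrip1 and Ivns1abp. Groups simulated without any change, with probe sets drawn independently, shared 0 on average over 100 simulations. Independent lists would share 0.000143 higher and 0.000429 lower. With 2 control arrays the controls could not be split, so shared controls may add to such a count. On the irradiated arrays wild type stood on the same side of both null genotypes for both genes, a difference that was not tested. The irradiated wild-type arrays are not those controls but carry the same numbers, 7 and 14. They may come from the same animals, so they are no independent check. Rpgrip1 stood at 251 in irradiated wild type against 1717 in Atm null and 1657 in Chk2 null, and Ivns1abp at 3301 against 1438 and 1169.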

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

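Of the tests in this part, those of dim probe sets and of Rpgrip1, the spike-in and actin covariates and the fit without 3 dim arrays were chosen only after the result was seen. So were the reading that every group must follow the spike-in level and the split between an open and an excluded explanation.

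Responses that differed between genotypes by a test of the difference itself stand out first. Between Chk2 null and wild type 83 probe sets differed, with Foxm1 (2.62), Cyb5r3 (2.58), Rrm1 (2.15), Tbpl1 (2.15), Cdk1 (1.93), Cks2 (1.92), Fen1 (1.91), Zfp746 (1.88), Nucb1 (1.86) and Nusap1 (1.86) higher in the log2 difference. Lower were Flvcr2 (-3.39), Zfp651 (-2.83), Ltbr (-2.64), Tmem144 (-2.31), Gdf2 (-2), Ccr6 (-1.78), Uqcr10 (-1.61), Pdrg1 (-1.54) and Clcn5 (-1.51). Other probe sets of Foxm1, Cyb5r3, Fen1, Nusap1 and Pdrg1 did not follow, and those of Uqcr10 disagreed with each other in direction. None of the 83 calls was left with the spike-in level or the actin ratio as a covariate, or with only the arrays of the contrast. Median list differences between the same genotypes were 1.35 for G2/M genes, 0.89 for DNA replication, 0.16 for double-positive thymocytes, -0.50 for p53 targets, -0.49 for B cells and MHC class II and -0.73 for myeloid cells. Between Atm null and wild type they were 0.80 for G2/M genes, 0.50 for replication, 0.27 for damage signalling, 0.13 for double-positive thymocytes, 0.12 for the ribosome and -0.31 for p53 targets. Between Chk2 null and Atm null they were 0.41 for G2/M genes and 0.32 for replication. None of these list differences was kept with an estimated correlation, where adjusted p lay between 0.342 and 0.793.

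Control probe sets, which no comparison of genes used, also moved with radiation in wild type and Atm null. The spike-in level rose by 1.25 log2 units in wild type and by 0.85 in Atm null, and the log2 ratio of 3' to 5' beta-actin by 0.48 and 0.49. In Chk2 null their means went the other way, the spike-in level from 12.1 to 11.55 and the linear actin ratio from 1.51 to 1.42, a fold of 0.683 and 0.944. This rested on mock array 3, at 12.61 and 1.65. In array pair 2 the spike-in level went from 11.58 to 11.51, and the actin ratio rose from 1.37 to 1.48. None of these differences was tested.

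The rise of p53 targets such as Aen and Bbc3 and the fall of G2/M genes such as Ube2c and Ccnb2 in irradiated wild type came with dimmer arrays and a higher actin ratio. With the spike-in level as a covariate the mean change of the p53 list was 0.94 ± 0.15 (SE), against 0.95 ± 0.08 before, and with the actin ratio 0.98 ± 0.13. Both stayed beyond 2 SE of 0. The G2/M list gave -1.11 ± 0.46 and -1.22 ± 0.42, against -1.19 ± 0.24, beyond 2 SE as the test required, but with the spike-in level the 95% interval on 5 degrees of freedom, -2.3 to 0.08, includes 0. The slope of a covariate came only from differences between the 2 arrays of a group. For the spike-in level the largest was that of mock Chk2 null, 1.02 log2 units, and the slope was carried over to the 1.25 units of wild type. So these fits cannot exclude brightness or RNA integrity as a cause in wild type. Dim probe sets were those with a mean signal below 597.125, the 75th percentile of the table. They made up 8319 of the 13984 tested, so most of them are not near background by this bound alone. Together they rose by 0.35 ± 0.09, and by 0.11 ± 0.11 with the spike-in level. In 4 of 6 groups the array with the higher spike-in level had the higher mean of these. So for dim genes such as Ltbr and Flvcr2 brightness and radiation cannot be told apart. A p53 response and a stop of division after radiation stay open beside a cell loss that was not measured. Calls of single genes ended under either covariate, where the SE of the list means grew.

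DNA replication genes such as Tk1 and Rrm2 shifted higher in irradiated Chk2 null, where mock array 3 was dim. Without that array the mean change of the list was 0.35 ± 0.17 (SE), against 0.32 ± 0.13 with it, which passes the bound of 2 SE narrowly while the 95% interval, -0.09 to 0.78, includes 0. With the actin ratio it was 0.36 ± 0.13, with an interval from 0.04 to 0.68. The mean log2 actin ratio differed little between these groups, at 0.59 in mock and 0.51 in irradiated Chk2 null. This covariate could therefore hardly move the list and does not decide about RNA integrity. A shift in the share of cycling cells, or in their transcription, stays open and was not tested.

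Rpgrip1 was higher in both null genotypes with and without radiation. The lowest of the 8 null arrays had 4.98 times the signal of the highest of the 4 wild-type arrays, of which both irradiated ones were dim, which argues against brightness. The largest fold between arrays of the same genotype was 1.55, so no genotype held arrays that differed by as much. In a mixed 129SvEv/C57B6 background an allele that differs between the founders of the lines may underlie it, but strain and genotype cannot be told apart without genotypes of the locus.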

How the results depend on the processing

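The spike-in and actin covariates and the fit without 3 dim arrays (mock Chk2 null 3, irradiated Atm null 12, irradiated wild type 7, with the dim irradiated wild type 14 kept), and the block together with an estimated correlation, were tests chosen only after the result was seen. With groups of 2 a lone array left by leaving out the other is assumed to vary like the other groups, and signals near background limit dim genes. Gene lists with the array number as a random block were not run, since camera has no such option. Where no cause is named, the cause was not tested.

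The 15 list calls of p53 targets, G2/M genes and DNA replication in the radiation responses and their differences kept their direction and call in all 24 other settings of camera with its preset correlation. With an estimated correlation 1 of the 15 was kept, p53 targets in Chk2 null, and 0 with the block as well, and fry called 8. In wild type the p53 median lay between 0.70 and 1.04, that of G2/M genes between -1.57 and -0.86 and that of replication between -0.68 and -0.37. Of named genes, 52 gene results were called, and over all settings 421 of their 832 values kept the call and 411 lost it, with no change of sign. The 102 not called stayed so in 1651 of 1682 values, with 31 gaining a call and 64 changing sign.

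Counts of calls moved as follows. The stricter filter, with fewer probe sets tested, gave 1106 in the wild-type response (2076 before), 1 for Atm null minus wild type (0 before) and 3 for Chk2 null in mock (5 before). Quantile normalization gave 1 for Atm null minus wild type, and in mock 5 for Atm null (3 before) and 2 for Chk2 null. Without the variance trend there was 1 in the Chk2 null response (0 before), 3 for Chk2 null minus wild type (83 before) and 3 for Chk2 null in mock. No filter gave 32 for Chk2 null minus wild type, and a pseudocount at the median 5 for Atm null in mock. With only the arrays of the contrast, which leaves 2 residual degrees of freedom for a response, the counts were 0 in wild type, 0 for Chk2 null minus wild type, and 1 and 3 in mock Atm null and Chk2 null.

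With the array number as a fixed replicate block, counts were 4713 in wild type, 102 in Atm null and 7 in Chk2 null. They were 253, 2210 and 1 for Atm null minus wild type, Chk2 null minus wild type and Chk2 null minus Atm null, and overlaps of calls (0 before) were 65, 7 and 7. A random block gave 9 for Atm null in mock. Apart from the block values beside the results, and double-positive markers in wild type (adjusted p = 0.0409 with the block, 0.0933 before, 0.253 with the block and an estimated correlation), the block changed no other list call. With the block and an estimated correlation the number of list calls in the 6 contrasts that a block allows was 0 (29 before).

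The spike-in covariate gave 0 in wild type, 0 for Chk2 null minus wild type and 1 for Chk2 null in mock, the actin covariate 0, 0 and 2, and leaving out the 3 dim arrays 452, 0 and 2. List calls over all contrasts, 39 before, were 1 with an estimated correlation, 23 by fry and 59 with the spike-in covariate.

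Wild-type calls were made anew in each setting, so the sets of genes behind the next medians differ. For genes that rose in wild type the median in Atm null (0.44 before) was 0.57 with a pseudocount of 1, 0.28 with one at the median, 0.38 with the stricter filter, 0.27 after quantile normalization and 0.61 for wild-type calls at 0.01. In Chk2 null (-0.08 before) it was 0.31 without the 3 dim arrays. For genes that fell the Atm null median (-0.22 before) was -0.234 with a pseudocount of 1, -0.197 with one at the median, -0.193 after quantile normalization and -0.233 without the trend. It was -0.181 with the block, -0.197 and -0.293 for wild-type calls at 0.10 and 0.01, and -0.231 without the 3 dim arrays. In Chk2 null (0.05 before) it was -0.0539 without them.

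Leaving out 1 array gave 42 to 1700 calls in wild type, 0 to 58 for Atm null minus wild type, 0 to 1318 for Chk2 null minus wild type, 2 to 9 and 1 to 3 in mock Atm null and Chk2 null. It gave 0 in the Atm null and Chk2 null responses and in their difference, and 32 to 44 list calls. Each of these fits also called the wild-type genes anew, so the sets of genes that rose or fell differed in size. Their medians ranged from 0.293 to 0.768 and from -0.38 to 0.871 for genes that rose, and from -0.362 to -0.197 and from -0.056 to 0.169 for those that fell, in Atm null and Chk2 null.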

Other observations

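The lists in this part were fixed before the data were examined. Of the other settings counted for them, the spike-in and actin covariates and the fit without 3 dim arrays were tests chosen only after the result was seen.

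Cell type markers also moved in irradiated wild-type thymocytes. All 19 myeloid genes were positive, with a median log2 change of 0.76, 2 passing and 7 when adjusted over the list alone, led by Csf1r (1.00) and Adgre1 (0.81). B cell and MHC class II genes (0.54, 13 of 15 positive, 5 passing), with Vpreb3 (1.44), Cd22 (1.08), Ms4a1 (1.08) and H2-DMb2 (1.00), rose as a list. So did mature single-positive markers (0.41, 3 passing), with Zbtb7b (1.10), Il6ra (1.07) and Gimap3 (0.94), and double-negative markers (0.57, 3 passing), with Il2ra (1.27), Notch1 (0.97) and Nrarp (0.77). In this order camera adjusted p was 0.0102, 0.0383, 0.0337 and 0.0443 (adjusted p = 0.333, 0.313, 0.412 and 0.287 with an estimated correlation). The myeloid call ended without irradiated wild type 14 (0.141). The other 3 ended without irradiated wild type 7 (0.0845, 0.0845 and 0.104), mock wild type 14 (0.0879, 0.215 and 0.117) or mock Chk2 null 3 (0.0526 each), and the irradiated arrays were dim. Over 24 other settings the myeloid call was kept in 23, that of B cells in 19 and that of mature cells in 18, and the double-negative call in 12 of 23. The double-negative call was lost with quantile normalization and with either covariate, its mean going from 0.55 ± 0.14 (SE) to 0.23 ± 0.22 with the spike-in level and 0.35 ± 0.23 with the actin ratio.

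NF-kB targets rose as a list (0.37, 4 passing), with Il2ra, Ccl4 (1.24), Nfkbib (0.85) and Cd83 (0.84). Some lists share members, so their shifts are not separate findings. Il2ra also leads the double-negative list, and Notch1 of that list is also among the p53 targets. Damage signalling genes fell as a list (-0.43, 4 lower and 1 higher), with H2ax (-1.44), Topbp1 (-1.20), Timeless (-1.08) and Ppm1d (0.93), and heat shock and unfolded protein genes fell (-0.22, 4 lower and 1 higher), with Hspe1 (-1.11), Hsp90aa1 (-0.88), Dnaja1 (-0.87) and Hspb1 (1.14). Camera adjusted p was 0.0449, 0.017 and 0.0449 (adjusted p = 0.387, 0.244 and 0.244 with an estimated correlation). The damage signalling call ended without mock Chk2 null 3 (0.0526). The NF-kB call ended without mock wild type 14 (0.195), irradiated wild type 7 (0.119), mock Atm null 5 (0.052) or mock Chk2 null 2 or 3 (0.0575 and 0.0545). The heat shock call ended without mock wild type 7 (0.108), irradiated wild type 7 or 14 (0.0781 and 0.0767), mock Atm null 5 (0.0503), irradiated Atm null 5 or 12 (0.0512 and 0.0518) or mock Chk2 null 3 (0.0531). Over 24 other settings the NF-kB and heat shock calls were lost in 13 each, and that of damage signalling in 3, all of these with quantile normalization among them.

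The remaining lists were not called in the wild-type response. Apoptosis genes had a median of -0.05 and a mean of 0.04 (adjusted p = 0.349 by camera), with Bcl2 (1.35), Bok (1.32) and Bcl2l11 (0.60) higher and Cycs (-0.84) lower. End joining genes had a median of -0.30 and a mean of 0.03 (0.395), with Polm (1.39) higher. Homologous recombination and Fanconi genes stood at 0.13 (0.964, camera's direction being lower), with Rad51ap1 at -1.06. Double-positive thymocyte markers stood at -0.19 (0.0933), with Cd24a at -1.02 and Rag1 at 0.71, NK or cytotoxic genes at 0.63 (0.183), with Gzma at -2.17 and Klrk1 at 0.92, and interferon genes at 0.12 (0.732), with Psmb8 at -1.01. Immediate early genes stood at 0.30 (0.143), with Egr3 at 1.25 and Fos at 0.99. Stroma with epithelium stood at 0.75 (0.117), with Col1a1 at 1.02, erythroid genes at 0.59 (0.652), with Gata1 at 0.88, glycolysis genes at -0.03 (0.158), with Pgk1 at -1.11, and ribosome genes at -0.05 (0.239), with Rpl41 at -1.49.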
